A study of Homo sapiens with 16 samples.

How the data were processed

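Per the labels' protocols, cells of breast cancer lines were infected with a lentivirus carrying dCas9-KRAB, selected for 2 weeks, and 50000 cells per library were treated with 100 nM Tn5 and amplified with 7 PCR cycles. Per the submitters' processing notes, BWA and the genome build hg38 were used for the ATAC-seq libraries; other steps are not given in the sources used here. Libraries were grouped by title into 8 lines with 2 replicates each. No file or column of the 4 lists belongs to a library, so no library entered a comparison. The depth of sequencing behind the variant lists is not given in them.

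The deposited lists hold positions. The GWAS list gives the chromosome and position of single-base sites, with no identifier in 307 of 4449 lines. The somatic list gives the chromosome, start and end of mutations. A further column of the somatic list, which ties entries to donors, was not used, and only counts and shares over at least 10 entries were written. The guide lists give the position of each 19-base guide, its design region and its sequence. The lists hold no read count, score or other measured value. How the authors chose variants, regions and guides is not given in the sources used here. The names of both variant lists give hg38 as their build. The guide lists carry a second set of coordinates in a text field, of a build not named, which was used only to compare the sets and never converted. GWAS guides come with a strand and somatic guides without.

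Gene symbols, gene spans and biotypes came from an NCBI RefSeq gene table of GRCh38.p14, the assembly also called hg38, with 19970 protein-coding genes on chromosomes 1 to 22 and X. This table has no strand, transcription start or exon. The promoter, exon, UTR and intron classes planned in advance could therefore not be formed. In their place, sites were classed as inside a gene span and as within 1 kb of either end of a protein-coding span, and distances of gene lists were measured to the gene span. No genome sequence was used here. To leave out long stretches not sequenced, only 100 kb windows with at least 1 somatic entry were used, 2830.1 Mb in all. Bases not sequenced inside such a window stayed in the count.

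SNPs with gaps of at most 500 kb were joined into loci. For SNPs by gene context, all SNPs of a chromosome were shifted together around its used windows (100000 random shifts, 10000 for alternatives; two-sided p), with 95% intervals from 10000 bootstrap draws of loci. Comparisons of shares or means between lists took the difference per chromosome, over chromosomes with at least 10 sites in both, weighted chromosomes equally, and flipped signs at random (100000 times, 10000 for alternatives, two-sided); the error given is the SE over chromosomes. Benjamini-Hochberg adjustment ran over 2 shift tests and 16 chromosome tests. Shares of bases were sampled every 50 bp.

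For 11 gene lists fixed in advance, the number of members with a SNP or somatic guide within 100 kb was compared with 10000 random lists of protein-coding genes matched on length decile and on tertile of gene density within 500 kb. The test was two-sided, with adjustment over 22 tests. Genes on X were left out for SNPs, since no SNP lies there. The random lists treat genes as independent although neighbours share SNPs and guides; counting neighbours within 500 kb once was therefore added as an alternative. Lists near somatic guides that share members with the drivers were also tested without these members, an alternative added after the results were seen. Named genes follow a rule written beforehand: the 10 loci with the most SNPs, each named by the protein-coding gene nearest its median SNP; in each list up to 4 genes with the most SNPs, or with at least 10 somatic guides, within 100 kb; and up to 10 genes with at least 10 somatic guides within 1 kb of an end. Only 4 genes met the last part. Other members of lists with 13 or fewer hits were named after their values were seen.

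Further comparisons were chosen after the lists had been seen: guides split by transcript label or by lower-case bases, entries inside regions against flanks (sign flips over regions, 100000, or 2000 for alternatives; 2000 bootstrap draws of regions; adjustment over 5 tests), genes with a labelled region, the overlap of the libraries (1000 shifts of the regions) and the strand of guides. The alternatives covered distances, distinct positions, single-base entries, other gene sets, equal locus weights, and leaving out each chromosome in turn.

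The tests were tested on simulated data. With no effect, 3.5% of 200 simulated SNP sets, 5% of 200 sets of 23 chromosome differences, 4% of 200 random lists of 20 genes and 5% of 20 mutation sets over the 1475 somatic regions gave p below 0.05. With planted effects the shares were 98% for loci drawn to gene spans, 99.5% for a mean difference of 1 SD, 100% for lists with 8 members placed near SNPs and 100% for 2 entries added per region, where a planted ratio of 16.4 came out as 16.3. Random genes were drawn singly and simulated mutations spread evenly, so lists of neighbouring genes and clustered mutations were not covered. Density ratios near 1, such as those of the GWAS regions, were not planted. Smaller effects were not planted for the other tests either, such as the 4 of 20 cell cycle genes near SNPs. The shares with planted effects therefore do not tell how often effects of the size reported here would be found. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.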

Results

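The series profiled open chromatin by ATAC-seq, in which the transposase Tn5 cuts accessible DNA, in 8 breast cancer cell lines that stably carried dCas9-KRAB, a catalytically dead Cas9 fused to a repressor domain. By sample title there were 16 libraries, 2 per line. MCF7 and ZR751 are oestrogen receptor-positive luminal lines, MDAMB361 is a luminal line with HER2 amplification, SKBR3 and HCC1954 are HER2-amplified lines, HCC1937 and MDAMB436 carry BRCA1 mutations, and MDAMB231 is a mesenchymal-like triple-negative line. The cell line field of the labels names MCF7 for all 16 libraries and so differs from the title in 14 of them. No value of any library was analysed here, so chromatin accessibility was not compared between lines and no sequencing depth is given. The 4 lists analysed cover the whole series: 4449 GWAS SNPs, 787212 somatic mutation entries, and 2 libraries of guide RNAs whose names tie them to these variant lists, with 20140 and 11798 guides. They hold positions and sequences, without read counts, scores or replicates, so no error given below comes from replicate libraries.

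The question put to the GWAS list was where its SNPs lie and which genes they lie beside. The trait behind the list is not named in the labels. The SNPs fell into 141 loci on 22 chromosomes when gaps of at most 500 kb were joined, with a median of 17 SNPs per locus and 16 loci of a lone SNP. The 10 loci with the most SNPs held 1720 of the 4449 SNPs (38.7%). All coordinates are hg38 and 1-based. The locus with the most SNPs, 376, spanned chromosome 7 from 91788502 to 92243559, and its median SNP lay in AKAP9, which encodes a centrosome and Golgi scaffold for protein kinase A. The next, with 294 SNPs, spanned chromosome 6 from 28468238 to 29447688 around TRIM27, a ubiquitin ligase gene beside the major histocompatibility complex. The MAST2 locus on chromosome 1, from 45688904 to 46347992, held 267 SNPs.

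DNAJC1 (146 SNPs), AMFR (126), CMSS1 (108), HSPA4 (106), GATAD2A (104), ABRAXAS1 (104) and ABT1 (89) named the other loci of this group. DNAJC1 and HSPA4 encode a co-chaperone and a chaperone, AMFR a ubiquitin ligase of the endoplasmic reticulum, GATAD2A a subunit of the NuRD chromatin remodelling complex, and ABRAXAS1 a partner of BRCA1 in DNA repair. The median SNP lay inside the gene span for AKAP9, TRIM27, MAST2, AMFR, CMSS1, HSPA4 and GATAD2A, and 85623 bp, 16201 bp and 9023 bp outside it for DNAJC1, ABRAXAS1 and ABT1. None of these 10 loci overlapped a gene of the 11 lists fixed before the data were examined. The GWAS guide library targeted between 10 regions near the AKAP9 locus, 2 without a gene label and 8 with a transcript label, and 38 near the ABT1 locus, 21 and 17 of the same kinds.

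**Figure D1:**
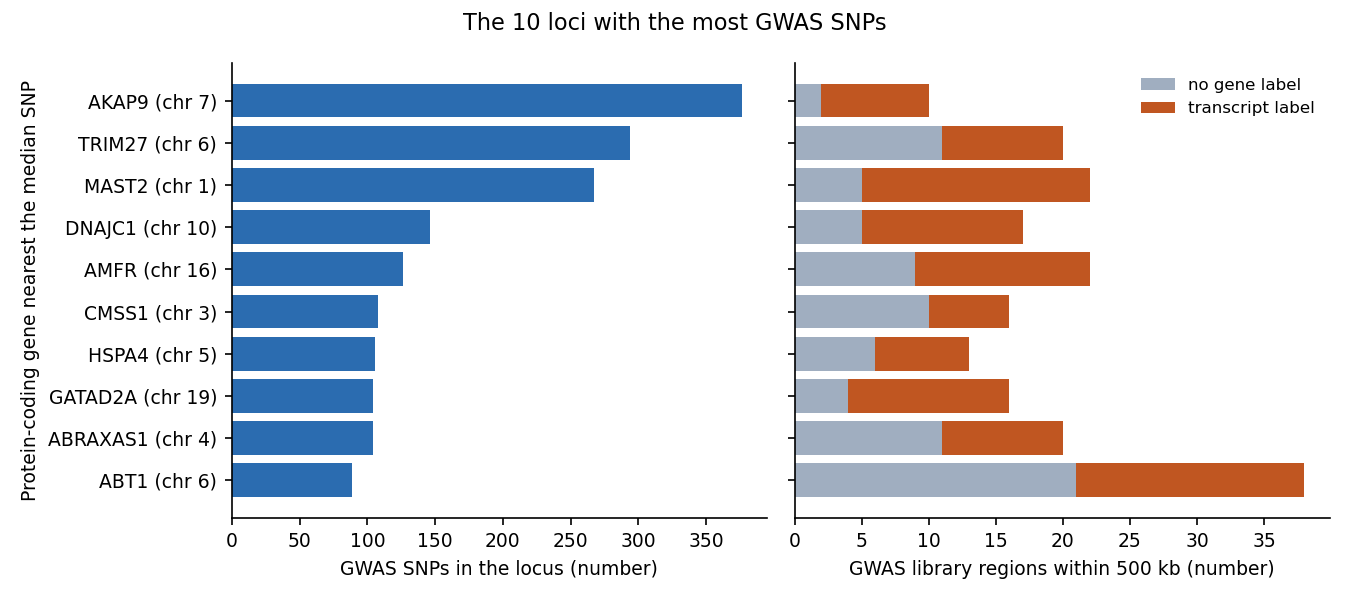
The 10 loci with the most GWAS SNPs, named by the protein-coding gene nearest the median SNP. The left bars give the number of SNPs in the locus, and the right bars the number of GWAS library regions within 500 kb, split by whether the region carries a transcript label. SNP number runs from 376 at AKAP9 to 89 at ABT1, and the ABT1 locus has 21 unlabelled and 17 labelled regions.

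Genes that the breast cancer genetics literature names at risk loci lay beside the SNPs far more often than matched genes. Of the 20 genes of that list, 13 had a SNP within 100 kb of the gene span, against 0.616 ± 0.768 (mean ± SD of 10000 matched random lists, adjusted permutation p = 0.0011, from the smallest p these lists can give). They were ANKLE1 and BABAM1 (64 SNPs each, in neighbouring genes), CASP8 (16), MAP3K1 (13), ESR1, FGFR2, LSP1, NTN4, PTHLH, RAD51B, TERT, TOX3 and ZNF365. BABAM1 encodes a subunit of a BRCA1-containing complex, CASP8 an initiator caspase and MAP3K1 a kinase upstream of JNK signalling. This list was chosen because association studies name its genes, so it is not independent of a GWAS list. Cell cycle genes were also near SNPs, with 4 of 20 against an expected 0.623 ± 0.775 (adjusted permutation p = 0.0203). These were TERT, the telomerase reverse transcriptase gene (6 SNPs), CDKN2C (2 SNPs), and the adjacent inhibitor genes CDKN2A and CDKN2B (1 SNP each). TERT is also a member of the risk locus list, as are CCND1, MYC and MDM4, which had no SNP in reach. The cell cycle list was not tested near SNPs without these shared members, so its call is not independent of the risk locus list. The call for the cell cycle list ended when neighbouring members were counted once, with 3 of 19 genes against 0.595 (unadjusted permutation p = 0.0195, adjusted 0.0858), and when the SNP had to lie inside the gene span (adjusted permutation p = 0.384).

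The other 9 lists did not pass the test near GWAS SNPs. Of 24 somatic driver genes 3 had a SNP within 100 kb (adjusted permutation p = 0.118), namely the kinase gene AKT1 (34 SNPs), MAP3K1 (13) and the oestrogen receptor gene ESR1 (10). MAP3K1 and ESR1 are also risk locus genes, and the drivers were not tested near SNPs without shared members. The call for the drivers appeared at 500 kb, where 6 genes had a SNP (adjusted permutation p = 0.0427). Of 14 hereditary breast cancer genes 2 had a SNP within 100 kb, BRCA2 (4 SNPs) and CHEK2 (2), with an adjusted p of 0.154. Luminal genes counted 2 of 17, ESR1 and XBP1 (2 SNPs), and housekeeping genes 2 of 13, SDHA (14 SNPs) and RPLP0 (2). Among liver genes 1 of 13, G6PC1 (3 SNPs), had a SNP in reach. None of 15 basal genes, 10 genes of the HER2 amplicon, 13 long neuronal genes or 14 immune genes did, with expected numbers between 0.458 and 0.577. With expected numbers this low, a shortfall was not detectable.

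Protein-coding gene spans held 2696 of the 4449 SNPs, 60.6% (95% bootstrap interval over loci 49.1 to 70.8). Shifting all SNPs of a chromosome together gave 46.6% on average, so the excess was 14 percentage points (permutation test by circular shift, two-sided, adjusted permutation p = 0.0229 over 2 tests). With every locus weighted equally the excess was 7.78 (adjusted permutation p = 0.0368). The call ended with the spans of all annotated genes, where 68.4% compared with 60.6% after shifting (permutation p = 0.113), and when chromosome 1 or chromosome 3 was left out (highest adjusted permutation p = 0.0602). Within 1 kb of either end of a protein-coding gene lay 187 SNPs, 4.20% (3.11 to 5.53), against 3.02% after shifting (adjusted permutation p = 0.0755). With every locus weighted equally this excess of 1.18 percentage points became 2.12 and passed (adjusted permutation p = 0.0162). With 2.5 kb in place of 1 kb the shares were 10.0% against 6.99% (permutation p = 0.0335). The excess within 1 kb fell to 0.723 without chromosome 4 (adjusted permutation p = 0.295) and passed without chromosome 16 (adjusted permutation p = 0.0479).

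The somatic list was described as a whole, with no entry taken singly. Its 787065 entries on chromosomes 1 to 22 and X were 95.8% single-base, and they came to 278 per Mb of the 100 kb windows that held any entry. Chromosome 8 had the highest density with 358 per Mb (95% Poisson interval 355 to 361), followed by X with 337 (334 to 339) and chromosome 20 with 319 (315 to 324). Chromosome 22 had the lowest, 218 per Mb (213 to 223), and chromosome 9 and 15 had 242 each. These intervals cover counting error only.

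**Figure D2:**
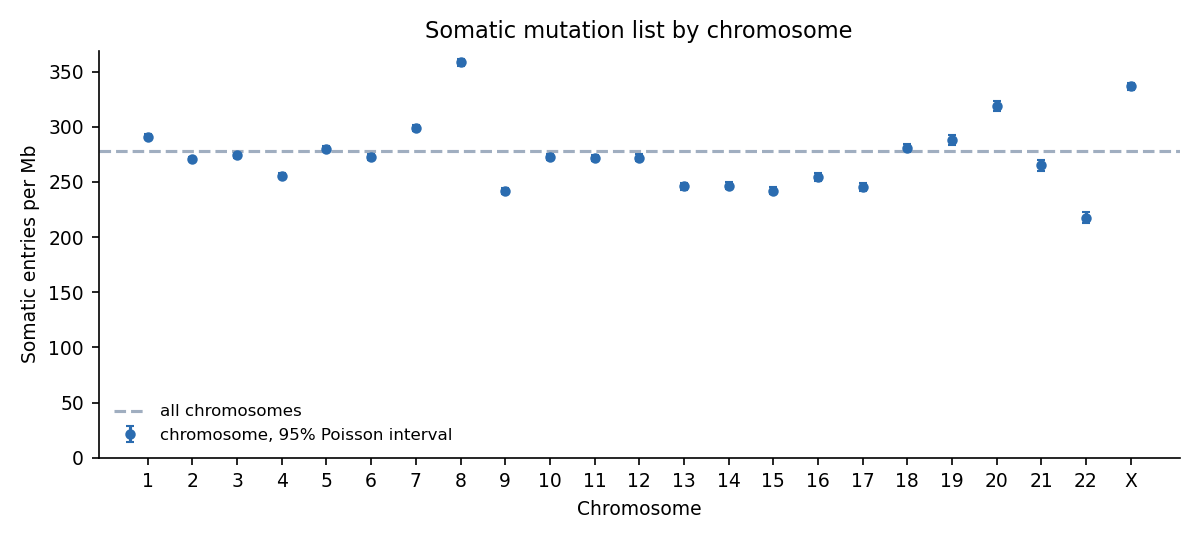
Somatic mutation entries per Mb on each chromosome. Points give entries per Mb of the 100 kb windows that hold an entry, bars the 95% Poisson interval, and the dashed line the density over all chromosomes, 278 per Mb. Chromosome 8 lies highest at 358 and chromosome 22 lowest at 218.

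Somatic entries lay inside protein-coding genes less often than the bases of the same windows did. Those bases include any that were not sequenced inside the windows. The share was 41% of entries against 44.4% of bases, with a mean difference over chromosomes of -3.28 ± 0.177 percentage points (SE, 23 chromosomes, lower in every chromosome; sign-flip permutation test, two-sided, adjusted permutation p = 2.29e-05 from the smallest p the flips can give). Close to gene ends, within 1 kb, the shares were 2.39% of entries and 2.54% of bases (difference -0.139 ± 0.0357, adjusted permutation p = 0.0013, higher in 2 of 23 chromosomes). No alternative moved either result across the threshold. Both errors and p-values cover variation between chromosomes and not between donors, since the column that ties entries to donors was not used.

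The 2 kinds of variants were then set against each other. GWAS SNPs lay inside protein-coding gene spans more often than somatic entries, 60.6% against 41%, with a mean difference of 13.7 ± 5.57 percentage points (SE, 21 chromosomes, higher in 15; adjusted permutation p = 0.0357 over 16 chromosome tests). The call ended when any of chromosomes 1, 3, 7, 14, 16, 17, 18 or 22 was left out, with differences between 11.1 and 16.4 over all chromosomes left out in turn and adjusted p up to 0.0694. Within 1 kb of gene ends the shares were 4.20% and 2.39% (difference 1.84 ± 1.03, adjusted permutation p = 0.0940), and the call appeared at 2.5 kb (difference 4.34, adjusted permutation p = 0.0301). The difference within 1 kb fell to 1.055 without chromosome 15, and passed without chromosome 20 (2.07, adjusted permutation p = 0.0494).

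The guide libraries had different layouts. The GWAS library held 1170 regions without a gene label, with 11539 guides, and 868 regions labelled with a gene symbol and a transcript, with 8601 guides. Of these regions 1141 and 853 had exactly 10 guides. The labels carried 698 gene symbols, of which 581 matched a current symbol and 40 an older one, giving 562 protein-coding genes and 36 lncRNA genes. The somatic library held 1475 regions, 1473 of them with 8 guides. The unlabelled GWAS regions all lay within 500 kb of a SNP, at a median distance of 161 kb (quartiles 49.6 and 314), and 866 of the 868 labelled regions did, at a median of 147 kb. Somatic regions lay at a median of 5498 kb from a GWAS SNP on the chromosomes that have any.

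Transcript-labelled guides sat at gene ends, and somatic guides did so in part. Within 1 kb of an end of a protein-coding gene lay 72.8% of transcript-labelled guides, against 4.20% of GWAS SNPs (mean difference 67.6 ± 2.13 percentage points, higher in 21 of 21 chromosomes, adjusted permutation p = 2.29e-05). Since their labels name a gene and a transcript, a place at gene ends may belong to the design of labelled regions. Their difference is therefore descriptive. Unlabelled guides, with 4.84%, did not differ detectably from the SNPs (difference 0.0425 ± 1.57, adjusted permutation p = 0.996). Somatic guides counted 28.5% near gene ends against 2.39% of the somatic entries (difference 25.5 ± 1.22, higher in 23 of 23 chromosomes, adjusted permutation p = 2.29e-05). They also lay inside gene spans more often, 50.7% against 41% (difference 8.64 ± 1.28, higher in 22 of 23, adjusted permutation p = 2.29e-05). How the somatic regions were chosen is not given, so both differences may belong to their design and are descriptive too. For the unlabelled and transcript-labelled guides the shares inside gene spans were 46.5% and 57.2% against 60.6% of SNPs, and neither difference passed (adjusted permutation p = 0.127 and 0.996).

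Transcript-labelled guides were richer in G and C than unlabelled guides. Mean GC content was 63.9% ± 13.6 (SD over 8601 guides) in transcript-labelled guides, 51% ± 13.5 in unlabelled guides and 52.4% ± 15.3 in somatic guides. Labelled guides exceeded unlabelled ones by 14 ± 1.15 percentage points (SE, higher in 22 of 22 chromosomes), and the GWAS library as a whole exceeded the somatic library by 4.84 ± 0.700 (22 of 22), both with an adjusted p of 2.29e-05. A run of TTTT, which ends transcription from the U6 promoter commonly used for guides, occurred in 2.73% of labelled, 5.65% of unlabelled and 5.89% of somatic guides. The difference between labelled and unlabelled guides was -2.76 ± 0.354 (adjusted permutation p = 2.29e-05) and that between libraries -1.60 ± 0.473 (adjusted permutation p = 0.000622). All guides were 19 bases long. Somatic guides come without a strand, and part of them had their PAM on the opposite strand, so their TTTT share holds for the written sequence only; GC content is the same on both strands.

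**Figure D3:**
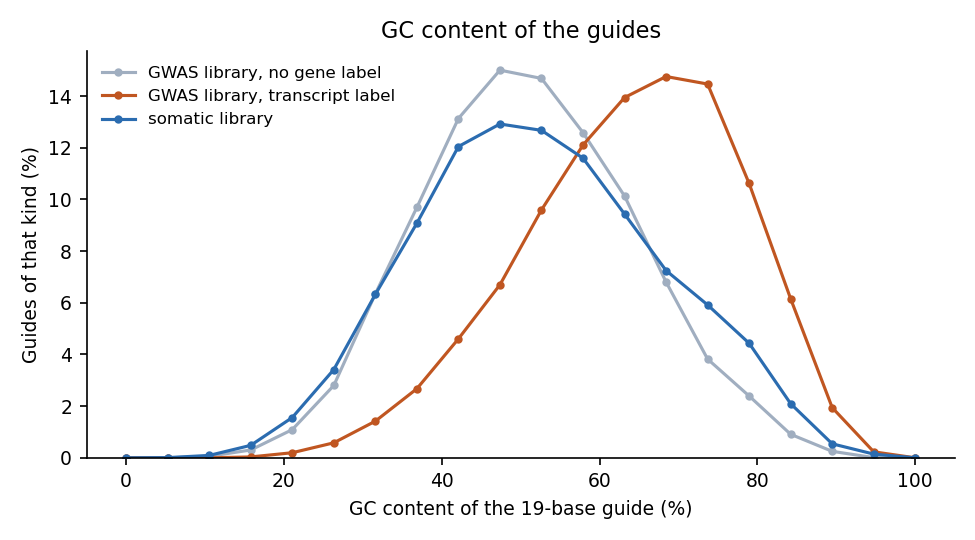
GC content of the 19-base guides, as the percentage of guides of each kind at each possible GC content. Transcript-labelled guides of the GWAS library (mean 63.9%) lie to the right of unlabelled guides (51%) and of somatic guides (52.4%).

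Recurrently mutated breast cancer genes stood beside the somatic library. Of 24 driver genes, 22 had a somatic guide within 100 kb of the gene span, against 4.61 ± 1.91 in 10000 matched random lists (adjusted permutation p = 0.0011, from the smallest p these lists can give), and 15 had a guide inside the span. The receptor kinase gene ERBB2 and ESR1 had 24 guides each in 3 regions, and CBFB, a transcription factor subunit gene, and the pioneer factor gene FOXA1 had 16 each in 2 regions. CCND1 and FGFR1 were the 2 members without a guide in reach. Genes of this list were chosen because they are recurrently mutated or amplified in breast tumours, so it is not independent of a mutation list. In the HER2 amplicon list 8 of 10 genes had a guide within 100 kb against 2.43 ± 1.37 (adjusted permutation p = 0.00293), but ERBB2, GRB7, IKZF3 and MIEN1 each counted 24 guides in 3 regions of the same stretch of chromosome 17. Counted once, these neighbours leave 1 gene, a list too small to pass in any case, so the call rests on a stretch that counts as a lone locus. It ended with guides inside the span (adjusted permutation p = 0.184) and was kept without the driver gene ERBB2, with 7 of 9 genes against 2.21 ± 1.29 (adjusted permutation p = 0.00953).

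Hereditary genes counted 7 of 14 against 2.79 ± 1.5 (adjusted permutation p = 0.0499), among them the kinase gene STK11 with 24 guides and BRCA1 with 16. Risk locus genes counted 8 of 20 against 3.51 ± 1.67 (adjusted permutation p = 0.0499), among them ESR1 with 24 guides and CASP8, MYC and RAD51B with 16 each. Both lists share members with the drivers: CDH1, NF1, PTEN and TP53 among the 7 hereditary genes, and ESR1, MAP3K1, MYC and TBX3 among the 8 risk locus genes. Without driver genes 3 of 10 hereditary genes had a guide against 1.92 ± 1.23 (adjusted permutation p = 0.637), and 4 of 15 risk locus genes against 2.74 ± 1.48 (adjusted permutation p = 0.71), so neither call held apart from the drivers. With all members, both calls lay at the threshold. Their adjusted permutation p was 0.0260 for both at 50 kb and 0.0147 and 0.0011 at 10 kb. With neighbouring members counted once in every list it was 0.0627 and 0.0594, although the excess did not fall (4.22 against 4.21, and 4.75 against 4.49). The other 7 lists did not pass. Luminal genes counted 5 of 18 (ESR1, ELF3, FOXA1, GATA3 and TBX3), cell cycle genes 5 of 20 with MYC and the inhibitor gene CDKN1B at 16 guides each, and long neuronal genes 6 of 14 with LRP1B at 16. Housekeeping genes counted 5 of 15, with RPLP0 and UBC at 16 guides each. Basal genes counted 2 of 15, with the adhesion receptor gene CD44 at 16, immune genes 2 of 15 and liver genes 1 of 14. The adjusted p-values of these 7 lists ran from 0.147 to 0.670.

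By guides within 1 kb of a gene end, 525 protein-coding genes had a somatic guide and 4 had at least 10. These were ADAM22 on chromosome 7, FOXA1 on chromosome 14 and ILF2 on chromosome 1, with 16 guides each, and TTC6 with 14. FOXA1 (37589552 to 37595249) and TTC6 (37595629 to 37842717) lie end to end, so the counts of these neighbours share guides. FOXA1 was the only gene among the 4 that belongs to a fixed list.

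**Figure D4:**
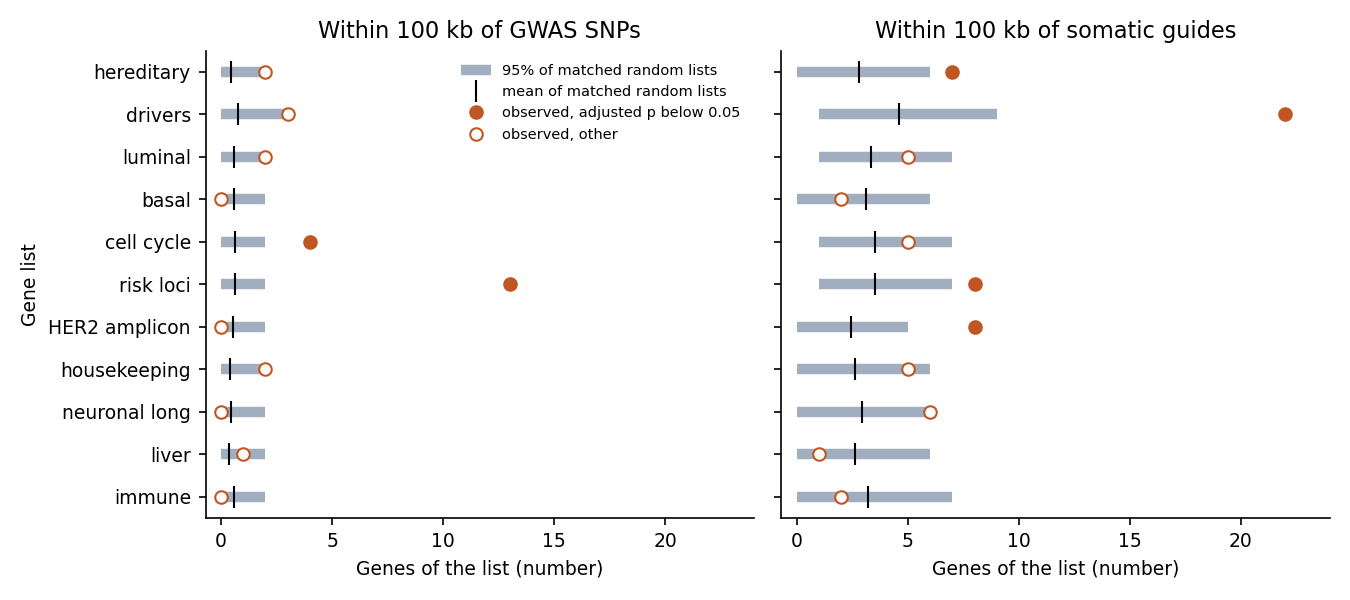
Number of genes of each of the 11 lists with a GWAS SNP (left) or a somatic guide (right) within 100 kb of the gene span. Circles are the observed numbers, filled where the adjusted p is below 0.05, ticks are the means and bars the central 95% of 10000 matched random lists. Risk locus genes reach 13 on the left and driver genes 22 on the right.

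Few listed variants lay at a guide. Within 20 bp of a guide of their own library lay 37 of the 4449 SNPs, 0.832% (95% Wilson interval 0.604 to 1.14), and 2030 of the 787065 somatic entries, 0.258% (0.247 to 0.269), with a median of 1 guide per covered site in both. The difference over chromosomes, 0.327 ± 0.154 percentage points (higher in 11 of 21), did not pass (adjusted permutation p = 0.0578). It passed at 100 bp (difference 0.442, adjusted permutation p = 0.0279) and at 500 bp (1.55, adjusted permutation p = 0.00118). Each share depends on the number of sites listed, 4449 against 787065, relative to the number of guides. The difference therefore does not show which library lies closer to its variants.

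The density of variants inside the targeted regions, from the outermost guides, was compared with flanks 2, 3, 5 and 10 kb to both sides, a comparison chosen after the lists had been seen. The 1475 somatic regions held 2610 somatic entries, 3.79 per kb against 0.273 in the flanks, a ratio of 13.9 (95% bootstrap interval 13 to 14.8; sign-flip permutation test over regions, adjusted permutation p = 5e-05 from the smallest p the flips can give). The somatic library is tied by name to this same list, so its regions may have been chosen for these entries. The ratio of 13.9 and its p-value are therefore no independent evidence of an excess. Transcript-labelled regions of the GWAS library held 142 entries, 1.52 times their flanks (1.18 to 1.92, adjusted permutation p = 0.00345). The ratio ran from 1.36 to 1.57 with a chromosome left out, and the call was kept. A single entry lay in 107 of these regions, and 12 held 2 or more, of which 10 held exactly 2. Part of the 142 entries thus rests on few regions. Somatic regions overlapped labelled regions in 31 cases and unlabelled ones in 24, and entries there stay in the counts. Unlabelled regions held 146, with a ratio of 1.26 (1.06 to 1.51, adjusted permutation p = 0.0288). That call ended with flanks at 20 and 50 kb (1.18, adjusted permutation p = 0.229), with single-base entries only (1.21, adjusted permutation p = 0.101), and without chromosome 6, 10 or 19 (ratios over chromosomes left out 1.18 to 1.34). The excess per region of labelled over unlabelled regions was 0.0299 entries (permutation p = 0.156). GWAS SNPs were not detectably denser in the unlabelled regions (23 SNPs, ratio 1.21, 0.675 to 1.87, adjusted permutation p = 0.617) or the labelled regions (15 SNPs, ratio 0.923, 0.459 to 1.51, adjusted permutation p = 0.8).

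**Figure D5:**
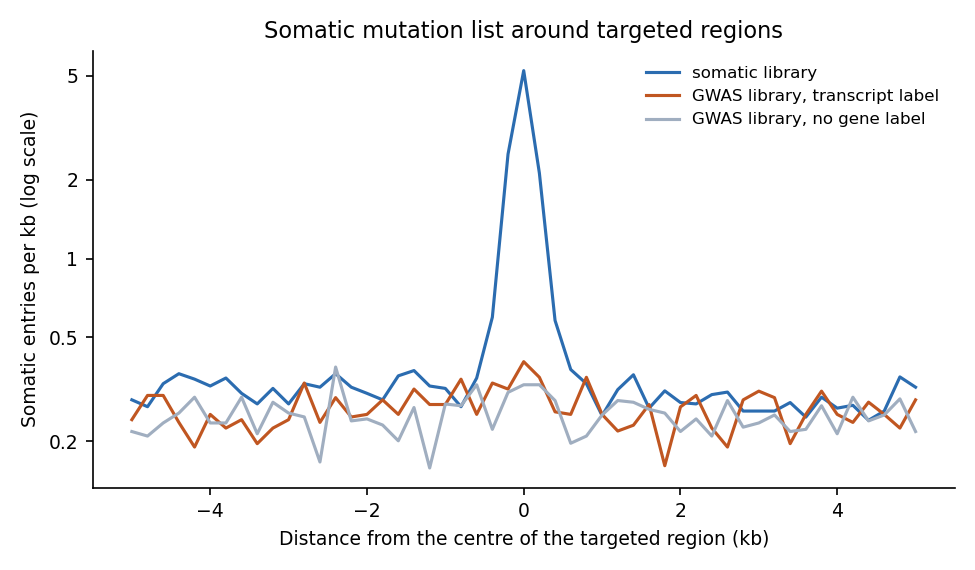
Somatic entries per kb in 200 bp bins within 5 kb of the centres of the targeted regions, on a log scale. The somatic regions rise to 5.23 per kb at their centre, while labelled and unlabelled GWAS regions reach 0.403 and 0.329 there.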

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

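The lists hold no reads, so any effect of sequencing depth on which variants were listed could not be assessed. No paired analysis was possible because no list holds a value of any library, so the replicate numbers pair nothing. The planned promoter of 500 bp upstream to 100 bp downstream of a start was not run without strand, and sites with a guide in place of guides were not run for the GWAS library, where no chromosome had 10 covered SNPs. Settings for flanks, gene spans as the distance, neighbouring members, driver members, labelled genes, overlap and PAM bases were chosen after seeing the data. Over 72 results, 181 alternatives other than leaving out a chromosome were computed, and 149 kept the direction and the side of the threshold, or the count within 1.5 times. Of 504 settings that left out a chromosome 460 did. The cause of the changes below was not tested, unless stated.

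For GWAS SNPs in gene spans, the excess of 14 percentage points was 7.78 with equal locus weights, still called, 7.84 with all annotated genes, where the call was lost, and 11.4 to 17.9 with a chromosome left out, lost without chromosome 1 or 3. The excess near gene ends was called only at 2.5 kb (3.01), with equal locus weights (2.12), and without chromosome 16 (range 0.723 to 1.42). GWAS minus somatic in gene spans ranged from 11.1 to 16.35 and was lost without 1, 3, 7, 14, 16, 17, 18 or 22. Near ends it was called at 2.5 kb (4.34), and without chromosome 15 or 20 it was 1.055 and 2.07, called for 20. Guides minus SNPs in gene spans ranged from -10.0 to -6.35 for unlabelled guides, called without chromosome 20, and from -2.24 to 2.25 for labelled guides, changing sign as the mean is near 0. Near ends unlabelled guides ranged from -0.534 to 1.04, also around 0. The difference in sites with a guide, 0.233 to 0.365 by chromosome, was called without any of 8, 9, 10, 11, 13, 15, 19, 20 or 22, and at 100 bp (0.442) and 500 bp (1.55).

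Near SNPs, members above expectation came to 4.01 for drivers at 500 kb (now called). Inside the span they came to 0.831 for cell cycle (lost), and to -0.192 for luminal, -0.103 for housekeeping and -0.0936 for liver genes, where sign changed because fewer members were hit. Near somatic guides, housekeeping genes fell to -0.626 at 50 kb, -0.723 at 10 kb and -0.418 inside the span. Immune genes rose to 0.15 at 10 kb and 0.559 inside it, basal genes to 0.201 inside it, and the HER2 amplicon fell to 1.63 inside it (lost). Counting neighbours once ended the call for cell cycle genes near SNPs (2.40, unadjusted p 0.0195). It left 1 gene of the HER2 amplicon near guides (0.766), too few to pass whatever the outcome. Near guides the calls for hereditary genes (4.22) and risk loci (4.75) were lost through the adjustment alone: their excess did not fall and their unadjusted p went from 0.0118 to 0.0114 and from 0.0136 to 0.0081. They passed at 50 kb and 10 kb, and were lost without members shared with the drivers (1.08 and 1.26), where luminal and cell cycle genes changed sign (-1.71 and -0.0488) and the HER2 amplicon passed (4.79).

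Labelled genes near minus far was 8.85 at 50 kb (lost); within 250 kb of a SNP, labelled hereditary genes and drivers fell below expectation (-0.0521 and -0.278). The ratio of somatic entries in unlabelled regions was 1.18 with far flanks and 1.21 for single-base entries (both lost), and 1.18 to 1.34 by chromosome, lost without 6, 10 or 19. SNPs in labelled regions ranged from 0.772 to 1.22, above 1 without chromosome 6. The GATAD2A locus held 161 SNPs when gaps of up to 1 Mb were joined, since it took in its neighbour.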

Other observations

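The tests of gene choice, library overlap, GC content, build, selection and strand reported here were chosen after the lists or the results had been seen; those of a constant offset and of neighbouring guides were set before their results were seen.

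Among protein-coding genes within 500 kb of a GWAS SNP, 562 of 1602 (35.1%) had a transcript-labelled region in the GWAS library. Genes within 100 kb of a SNP had one in 257 of 631 cases (40.7%) and genes 100 to 500 kb away in 305 of 971 (31.4%). The mean difference over 16 chromosomes was 10.5 ± 3.45 percentage points (SE, higher in 13; sign-flip permutation p = 0.00844), and with the division at 50 kb it was 8.85 (permutation p = 0.0881). Of the 17 risk locus genes in reach 7 were labelled (BABAM1, CASP8, MAP3K1, MRPS30, MYC, NTN4 and PTHLH), against 7.45 ± 2.04 in matched lists. MYC and CASP8 had 3 labelled regions each and the cell cycle inhibitor gene CDKN2C had 4, and no gene had more. Hereditary genes counted 2 of 4 (BRCA2 and NF1), drivers 3 of 6 (MAP3K1, MYC and NF1), luminal genes 1 of 2 (XBP1) and cell cycle genes 2 of 7 (CDKN2C and MYC). The 1 basal gene, 2 housekeeping genes and 1 liver gene in reach had none, no gene of the HER2 amplicon, long neuronal or immune lists was in reach, and the adjusted p was 1 for every list.

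The 2 libraries met more often than random placement along the chromosomes gives. Of the 1475 somatic regions, 24 overlapped an unlabelled GWAS region, against 0.585 on average when the somatic regions were shifted along their chromosomes, and 31 overlapped a labelled one, against 0.451 (both permutation p = 0.001, the smallest that 1000 shifts can give). The shifts did not keep the position of regions relative to genes. Within 1 kb of gene ends lay 72.8% of labelled and 28.5% of somatic guides, against 4.84% of unlabelled guides. For labelled regions the p-value therefore cannot tell shared targets from a common placement at gene ends. Unlabelled guides lay there about as rarely as GWAS SNPs, 4.20%. This argues against placement at gene ends as the source of the 24 overlaps with unlabelled regions. Placement at another kind of site common to both libraries was not tested. The libraries had 64 guide sequences in common as written, all at targets on the plus strand. At 79 targets on the minus strand the somatic guide was the reverse complement of the GWAS guide, so single targets were shared.

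The ratio of somatic entries in GWAS library regions to their flanks was 1.38 (95% bootstrap interval 1.00 to 1.87), 1.46 (1.17 to 1.79) and 1.29 (1.02 to 1.59) in the regions with low, middle and high guide GC content, in 3 groups of near-equal size. Guides with lower-case bases, the usual mark of repeats, were 21.9% of the unlabelled and 9.53% of the labelled GWAS guides (difference -9.95 ± 1.82 percentage points, adjusted permutation p = 0.00024).

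Few GWAS SNPs lay in the regions of the GWAS library. By the hg38 positions 77 SNPs were within 250 bp of a guide. If the SNP positions were in the build of the guides' second coordinates, more should lie near guides there, but only 38 did. With regions placed at SNPs, a constant displacement between the lists should give many more at another offset of up to 20 kb. The highest of 80 other offsets gave 111, with a median of 80.5, and 53 gave at least 77. The listed positions thus showed no excess over other offsets, and whether regions were placed at SNPs is not known. The counts therefore cannot decide whether the lists are displaced. The SNP density in all GWAS regions was 1.08 times that of their flanks (0.709 to 1.52), consistent with regions having been chosen around SNPs without regard to whether they hold one. No biological explanation was tested.

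Somatic entries concentrated in the somatic regions. The targeted stretch held exactly 2 entries in 1003 of the 1475 regions, 1 in 254 and 0 in 113, so 75.1% held at least 2, and within 250 bp of it, a margin chosen after the counts were seen, 96.5% did. This is consistent with regions wider than the stretch having been chosen for at least 2 entries, but the counts are part of the concentration itself, and the rule of choice stays open. If a general excess of entries in regulatory DNA gave the whole ratio, regions at gene ends should show a similar one. The transcript-labelled GWAS regions reached at most 1.92 by their upper bound, below 13, the lower bound in the somatic regions. An excess of that size was thus not seen in labelled regions. The comparison cannot decide whether a smaller general excess adds to the ratio, since the somatic regions may have been chosen for their entries. The sets also differ in place, with 72.8% of labelled and 28.5% of somatic guides within 1 kb of gene ends. The ratio in the somatic regions may reflect how they were chosen, and gives no mutation rate. Open chromatin of the cell lines as a basis of the choice was not tested.

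A large share of the somatic guides had no PAM, the GG motif that Cas9 needs, after their written sequence. Where neighbouring guides spelled out the bases on both sides, 70 of 121 had GG after only, 46 (38%, 95% Wilson interval 29.9 to 46.9) had CC before only, 5 had both and 0 neither, while of 445 such GWAS guides for the plus strand 413 had GG after only, 0 had CC before only, 30 had both and 2 neither. With bases from GWAS guides only, 45.8% of 24 had CC before only. Wrong positions of guides relative to their neighbours are argued against, since 100% of the 314 pairs of neighbouring somatic guides that share 3 or 4 bases agreed in them. A displacement common to neighbouring guides would leave this agreement unchanged, so the pairs do not test for one. At targets that the GWAS library has on the minus strand, 79 of 79 somatic guides were the reverse complement of the GWAS guide, and at plus-strand targets 64 of 64 were identical. This is consistent with somatic guide sequences having been written on the reference strand whatever the strand targeted. No biological explanation applies.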
